A study of Homo sapiens with 24 samples.

How the data were processed

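The series measured shRNA inserts amplified from genomic DNA of PC-3, LNCaP, 22Rv1 and V16A cells in 24 libraries: 4 lines, 3 days (0, 8 and 16 after selection) and 2 replicates. Per the labels' protocols, cells were infected with a lentiviral shRNA library at a low multiplicity of infection, selected with puromycin at a dose set per line, split and passaged, and the inserts were amplified by PCR and sequenced. The labels do not state whether the 2 replicates were separate infections or cultures split after selection.

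The authors deposited 1 table of whole-number counts per shRNA and library, with the target of each shRNA. Per the submitters' processing notes, MAGeCK 0.5.4 and GRCh37 were named, with no role given. How reads were assigned to shRNAs, and which mismatches were allowed, is not given in the sources used here. Each of the 24 count columns matched 1 sample by its title. No row lacked a target. The numbers of the table's entries run to 12464 and 1158 of them are absent; those were not analysed here.

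Amplified reads carry no molecular identifiers, so counts hold PCR noise as well as sampling noise, and depth alone does not give the precision. Total counts of 1394861 to 6094499 over 11306 shRNAs gave medians of 105 to 488 per shRNA. The common biological coefficient of variation was 0.311. A change common to most of the library cannot be seen after scaling to its centre.

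Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, which removed 0 shRNAs, and a quasi-likelihood fit of 12 group means to all 24 libraries with 12 residual degrees of freedom. Contrasts were day 16 against day 0, day 8 against day 0 and day 16 against day 8 in each line, the mean of the 4 day 16 contrasts, the 6 differences between lines, and LNCaP, 22Rv1 and V16A against PC-3. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and tests are two-sided unless stated. Log2 changes of shRNAs are given with the SE of the fit.

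Targets with at least 2 shRNAs, 2460 with controls, were scored by robust rank aggregation with alpha 0.25, the method on which MAGeCK is built, written here in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. It was run one-sided for each direction on signed edgeR p-values, with p from 1e+06 random draws and adjustment over targets within each direction. The size given for a target is the median log2 change over its shRNAs with the SD over shRNAs, and for a difference between lines the median over its shRNAs of their own differences.

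Gene names could be used for the positive controls alone. The 20 gene lists fixed beforehand were written for host genes of linear targets, and since the table does not pair those targets with genes the lists were applied to the 83 positive-control genes, with the linear targets as background. This departs from the planned design. Because 67 of the 83 genes have 1 shRNA, named control genes are given by the edgeR test of single shRNAs. Lists with at least 3 positive-control genes were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM averaged per target, and with fry as an alternative, which tests whether a list moves one way and does not compare it with other genes. These 5 lists were ribosomal proteins, proteasome, spliceosome and splicing factors, translation factors and tRNA synthetases, and nuclear pore and transport. All positive controls and the positive controls in no list were added, which made 35 list tests over 5 contrasts. Of the other 15 lists, 6 had 1 or 2 positive-control genes: RNA polymerases and general transcription, DNA replication, mitosis, circular RNA biogenesis factors, mitochondrial respiration, and vesicle coat. The other 9 had 0 positive-control genes, so they gave no result, among them cell cycle drivers, cell cycle inhibitors and tumour suppressors, PI3K and mTOR, receptor kinases and MAPK, chromatin regulators, DNA damage response, ubiquitin ligases, and lipid metabolism. The table marks the 83 genes as positive controls. They are taken here as genes whose loss should lower abundance, so their direction is not independent evidence.

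The rule for names was fixed with the designs, the gene lists and most of the alternatives before the data were examined: per line and for the mean, called targets with the largest median change of the called sign in both replicates, the most negative and most positive called targets of each difference between lines, and for each list up to 4 members with the smallest depletion p. Identifiers without gene names limited this to 2 in each direction. MYC, FOXA1 and CSNK1G3, which the rule also asked for, are not named in the table, and no value is given for them. Other genes the rule asked for are not reported here.

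Controls were compared by a two-sided permutation test of the difference of medians with 100000 draws, classes by Fisher's exact test, and pairs by Pearson and Spearman correlation with 100000 permutations. Overlaps between lines were set against independent lists. Whether replicate numbers pair the libraries was checked before the fits were compared, by the correlation of deviations from group means across shRNAs. Days 8 and 16 with the same number correlated at 0.122 to 0.253 in the 4 lines and were taken as paired, while day 0 correlated at −0.0213 to 0.0245 with day 8 and at −0.00746 to 0.0194 with day 16 and was not.

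The fits were tested on simulated data for PC-3 day 16 against day 0, with counts drawn from the real means. With abundance set to 0.25-fold, 82.0% of changed targets among 2460 and 90.0% of changed shRNAs among 11306 were recovered, and at 0.5-fold 10.0% and 36.8%. At 2-fold and 4-fold abundance, 26.0% and 90.0% of targets and 56.4% and 92.4% of shRNAs were recovered. The changed targets all had 5 shRNAs, and every shRNA of a target was given the same fold. Of the linear targets 560 of 933 have 5 shRNAs, and shRNAs of 1 real target agree less, so these shares may overstate recovery. With nothing changed, 0 targets and 0 shRNAs were called. There each shRNA was drawn on its own, so this run does not check false calls where shRNAs of 1 target move together. All groups were given the same spread per shRNA, as the fit assumes. The run therefore does not check false calls from unequal spread between groups either. Alternatives covered scaling, count filters, DESeq2 1.42.0, the 6 libraries of a line alone, a replicate block, thresholds, target scores, shRNAs per target, list tests and leaving out each library. Figures were drawn with matplotlib 3.10.9.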

Results

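A pooled short hairpin RNA (shRNA) library was carried through 4 prostate cancer cell lines, and the shRNA inserts in genomic DNA were counted at day 0, day 8 and day 16 after drug selection. PC-3 is a line from a bone metastasis, LNCaP is from a lymph node metastasis, and 22Rv1 is a xenograft-derived line. V16A is described here only as a prostate cancer line, as in the labels. Each line and day had 2 replicate libraries, which made 12 groups and 24 libraries. The labels do not state that the replicates were separate infections, so the edgeR p-values of shRNAs measure the spread between these samples, which may be technical. That spread is pooled per shRNA over the 12 groups, so a p-value of 1 line does not measure that line's own spread. The SD of the replicate difference ran from 0.263 log2 units in 22Rv1 at day 0 to 1.30 in LNCaP at day 16. Calls may therefore be too many in a line of wide spread and too few in a line of narrow spread. The p-values for targets, control medians, classes and overlaps are taken over shRNAs or targets. They do not measure the spread between libraries.

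The count table held 11306 shRNAs. Of these, 7171 shRNAs aimed at 1508 circular RNAs and 4029 aimed at 933 linear RNAs. A further 100 shRNAs against 83 genes were positive controls, and 6 shRNAs against RFP, luciferase and lacZ were negative controls. A circular and a linear target of the same number made 891 pairs, 617 circular targets had no linear partner, and 42 linear targets had no circular partner. Circular and linear targets carry study identifiers that the table does not pair with gene names, so at most 2 that rose and 2 that fell are named per comparison.

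Total counts ran from 1394861 to 6094499 per library and the median count per shRNA from 105 to 488. The spread of abundances grew with time in culture. The Gini coefficient, 0 for equal counts over all shRNAs, was 0.300 to 0.328 at day 0 and 0.363 to 0.452 at day 16. At most 4 shRNAs had no count in a day 0 library, against 6 to 83 at day 16. Replicate libraries correlated at r = 0.955 across shRNAs in 22Rv1 at day 0 and at r = 0.654 in LNCaP at day 16, the highest and lowest of the 12 groups; shRNAs are not independent replicates. Replicate pairs differed by 4.05 to 64.7 times the chi-square of sampling noise per degree of freedom. Counts hold PCR noise as well, so the size of this excess does not by itself show separate cultures. Replicates of the same number deviated together at days 8 and 16, at r = 0.122 to 0.253 across shRNAs in the 4 lines. Between day 0 and day 8 this was −0.0213 to 0.0245. Noise made anew in each library would not carry over between days, so these values argue against it as the only source at days 8 and 16. They do not show separate infections.

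The control shRNAs ask whether shRNAs against the genes chosen as positive controls lose abundance in each line. Positive-control shRNAs fell against negative-control shRNAs in all 4 lines by day 16. The difference of medians was −1.24 log2 units in PC-3, −1.04 in LNCaP, −1.39 in 22Rv1 and −1.66 in V16A (two-sided permutation test over shRNAs, adjusted p = 0.00418, 0.0141, 0.00107 and 0.000292). The same difference was present at day 8, at −1.21, −1.13, −1.68 and −1.44 (adjusted p = 0.00173, 0.00154, 6.5e-05 and 6.5e-05); in 22Rv1 and V16A the raw p was 1e-05, the smallest the permutations can give. Between day 8 and day 16 the differences were −0.09, −0.23, 0.24 and −0.15, none past the threshold (adjusted p from 0.238 to 0.672). The median positive-control change per library at day 16 was −0.87 ± 0.03 in PC-3, −0.78 ± 0.06 in LNCaP, −0.99 ± 0.22 in 22Rv1 and −1.20 ± 0.09 in V16A (SD, n = 2). The circular class was at 0.02, 0.04, 0.02 and 0.02 and the linear class at −0.10, −0.10, −0.10 and 0.00.

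**Figure D1:**
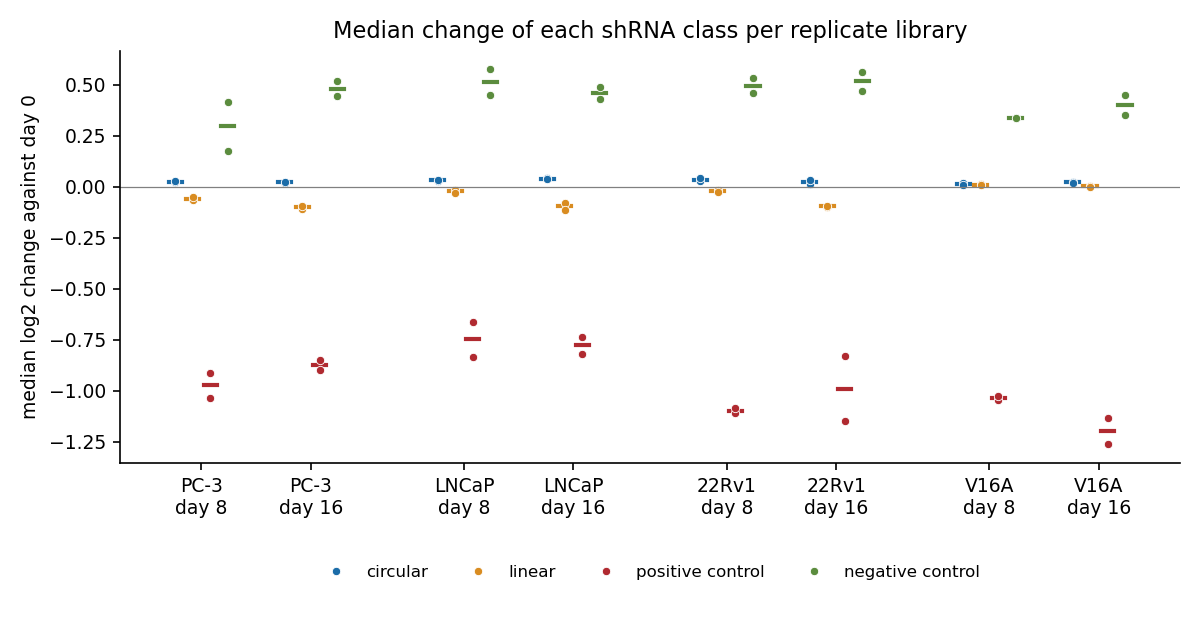
Median log2 change from day 0 (vertical axis) of circular, linear, positive-control and negative-control shRNAs in each line at day 8 and day 16. Points are single replicate libraries and bars are the mean of 2; positive controls lie below the other classes in every line.

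The negative-control shRNAs were not at the centre of the library. Averaged over the 4 lines, 1 luciferase shRNA rose by 1.02 ± 0.13 (SE) and 1 lacZ shRNA by 0.98 ± 0.22 (edgeR adjusted p = 1.89e-06 and 0.000837), and the other luciferase shRNA rose by 0.50 ± 0.20 (adjusted p = 0.0438). All changes are relative to the TMM centre of the library. Scaling to the 6 negative controls instead shifted the median of all shRNAs by −0.42 in PC-3, −0.65 in LNCaP, −0.40 in 22Rv1, −0.47 in V16A and −0.49 in the mean of the lines; total-count scaling shifted LNCaP by −0.14. Under their own scaling the negative-control shRNAs move towards 0 by construction. Their median was then −0.05 in PC-3, −0.26 in LNCaP, 0.12 in 22Rv1, 0.10 in V16A and −0.13 in the mean. In each case it stayed above the median of all shRNAs, which also follows by construction, since scaling shifts all shRNAs of a library nearly alike.

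Averaged over the 4 lines, shRNAs against the machinery of translation and splicing were lost by day 16. EIF3B, a subunit of the initiation factor that recruits the small ribosomal subunit, fell by 1.23 ± 0.12 on the log2 scale (SE, adjusted p = 5.81e-08). RPL23A, a protein of the large ribosomal subunit, fell by 1.84 ± 0.19 (adjusted p = 7.66e-08), and RPS14, of the small subunit, fell by 1.38 ± 0.16 (adjusted p = 5.95e-07). SFRS1, a splicing factor, fell by 2.67 ± 0.32 (adjusted p = 6.11e-07), and PSMD12, a regulatory subunit of the proteasome, fell by 1.61 ± 0.23 (adjusted p = 5.29e-06). In all, 66 of the 100 positive-control shRNAs, against 57 of 83 genes, fell and 0 rose. In the library 26.2% of linear and 19.6% of circular shRNAs fell. EdgeR gave these counts, and 70 positive-control shRNAs fell when adjusted over the list alone. These calls for the genes named held without any 1 of the 16 libraries.

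The gene groups were described by list. Each list was set against linear targets and not against the other positive controls, so a pass does not set 1 function apart. The median over all positive controls was −0.95. Of 17 spliceosome shRNAs against 15 genes, 15 fell, 15 adjusted over the list alone (median −1.23, camera adjusted p = 8.87e-05); PLRG1 fell by 1.53, DDX23 fell by 1.43 and SNRPD2 fell by 1.33. All 6 translation-factor shRNAs against 5 genes fell, 6 adjusted over the list alone (median −1.37, camera adjusted p = 0.00961); EIF5B fell by 1.77, EIF3C fell by 1.59 and EIF3D fell by 1.30. Of 31 ribosomal-protein shRNAs against 24 genes, 17 fell, 18 adjusted over the list alone (median −0.72, camera adjusted p = 0.0147); RPL7 fell by 1.68 and RPL32 fell by 1.48. Of 13 proteasome shRNAs against 9 genes, 9 fell, 10 adjusted over the list alone (median −0.69, camera adjusted p = 0.0263), and PSMC5 fell by 1.27 and PSMB2 fell by 1.18. The proteasome call was lost with an estimated correlation (adjusted p = 0.0881 with an estimated correlation), and the ribosomal, spliceosome and translation calls held (adjusted p = 0.0286, 0.0119 and 0.0364). Of 100 splits of the libraries, the real one included, 5 gave a camera p as small for spliceosome and 17 for proteasome. For ribosomal proteins 3 did so and for translation factors 1. By the rule set beforehand, 5 or more of the 100 splits left chance as an account, which held for spliceosome and proteasome. The other splits put 2 to 6 day 16 libraries in the first group, so some carry part of the real change. The camera p also has no direction, so the splits do not settle chance for any list.

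The nuclear transport list did not pass by camera (adjusted p = 0.196). Of its 5 shRNAs against 3 genes, 2 fell, 2 adjusted over the list alone: KPNB1, the import receptor importin beta, fell by 1.35 ± 0.18 and 1 of 2 shRNAs against RAN, the GTPase that drives transport, fell by 1.43 ± 0.34, with the other at 0.22 (adjusted p = 0.177). The lower of 2 shRNAs against NUP205, a scaffold protein of the pore, was at −0.52 ± 0.25 (adjusted p = 0.0930). The 6 lists with 1 or 2 positive-control genes were not tested as groups. COPB1, a subunit of the COPI vesicle coat, fell by 1.90 ± 0.39 while ARCN1 of the same coat was at −0.42 (adjusted p = 0.181). HNRNPC, an RNA-binding protein, fell by 2.79 ± 0.46 and with SFRS1 made up the list of circular RNA biogenesis factors, 2 of 2 falling. CDC23, a subunit of the anaphase-promoting complex, fell by 0.78 ± 0.19 and C14orf2, a mitochondrial protein, fell by 0.99 ± 0.20. POLR2D, an RNA polymerase II subunit, was at −0.45 (adjusted p = 0.139) and RPA1, the DNA replication protein, at 0.04 (adjusted p = 0.894).

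**Figure D2:**
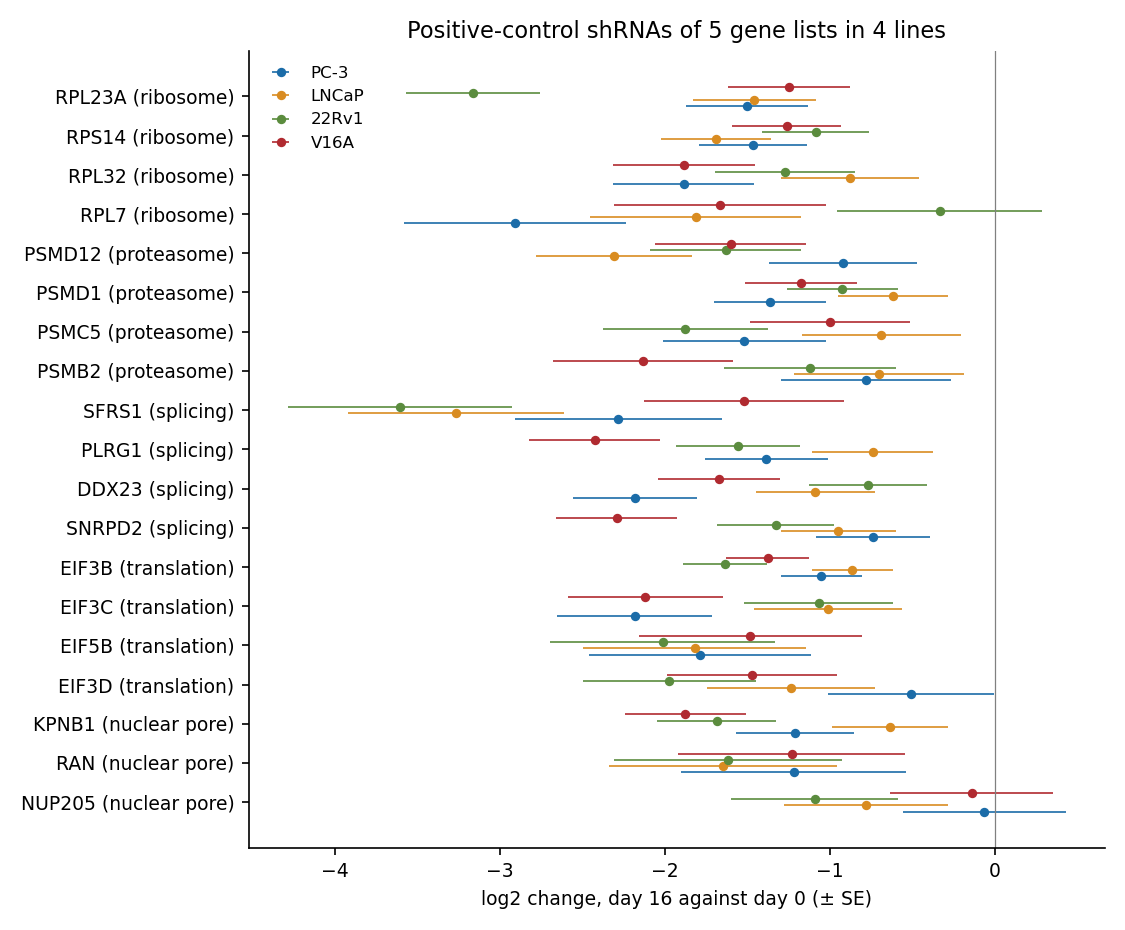
Log2 change from day 0 to day 16 (horizontal axis) of 19 positive-control shRNAs from 5 gene lists, with 1 point per line and bars for the SE of the edgeR fit. EIF3B and RPS14 are below 0 and past the threshold in each line.

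EIF3B, RPS14 and CCT3, a subunit of the TRiC chaperonin, were the 3 shRNAs that fell in all 4 lines at day 16; 12 fell in 3 lines, 10 in 2, 19 in 1 and 56 in none. EIF3B changed by −1.05 in PC-3, −0.86 in LNCaP, −1.63 in 22Rv1 and −1.38 in V16A, RPS14 by −1.47, −1.69, −1.09 and −1.26, and CCT3 by −1.25, −0.97, −1.21 and −0.86. The EIF3B call ended without PC-3 day 16 replicate 1 (adjusted p = 0.0579), LNCaP day 0 replicate 1 (0.0503) or replicate 2 (0.0599), or V16A day 0 replicate 1 (0.0554). The RPS14 call ended without PC-3 day 16 replicate 1 (0.0518), without any 1 of the 4 22Rv1 libraries (0.0901 to 0.152), and without V16A day 0 replicate 1 (0.177), day 0 replicate 2 (0.110) or day 16 replicate 2 (0.263). The CCT3 call ended without LNCaP day 0 replicate 1 (0.0574) and without any 1 of the 4 V16A libraries (0.0599 to 0.193).

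Positive controls named with a fall in this and the next paragraphs on single lines at day 16 are those whose call held without any 1 library of the comparison, a choice made after the values were seen. In PC-3 at day 16, DDX23, a spliceosomal helicase, fell by 2.18 ± 0.37 (SE, adjusted p = 0.000338), CCT8, a chaperonin subunit, fell by 2.50 ± 0.50 (adjusted p = 0.00127), and EIF3C fell by 2.18 ± 0.47 (adjusted p = 0.00236). VCP, the segregase that extracts ubiquitinated proteins, fell by 2.40 ± 0.53 (adjusted p = 0.00267) and SNRPD1, a core protein of spliceosomal particles, fell by 1.58 ± 0.34 (adjusted p = 0.00256). Without 1 library the EIF3C value ranged from −3.487 to −1.501. In all, 21 positive-control shRNAs fell, 24 adjusted over the list alone, and 15 of the 21 calls ended without 1 library. By edgeR 12.5% of linear and 7.29% of circular shRNAs fell, against 21% of positive controls. Spliceosome members fell in 6 of 17 shRNAs (7 adjusted over the list alone, camera adjusted p = 0.00172) and ribosomal members in 5 of 31 (5 adjusted over the list alone, camera adjusted p = 0.0522). With PC-3 day 0 replicate 2 or day 16 replicate 1 left out the ribosomal value was 0.0375 or 0.0172. Translation factors fell in 2 of 6 (4 adjusted over the list alone, camera adjusted p = 0.0280), a call lost with an estimated correlation (adjusted p = 0.0653 with an estimated correlation) and without PC-3 day 16 replicate 1 (0.0645). Proteasome members fell in 2 of 13, 2 adjusted over the list alone (camera adjusted p = 0.455), and nuclear transport in 1 of 5 (camera adjusted p = 0.468).

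Over the whole library in PC-3, 1046 shRNAs fell and 936 rose, 17.5% of those tested; scaled to the negative controls, 2135 fell and 198 rose, which moved the share of lower calls from 52.8% to 91.5%. Leaving out day 0 replicate 1, day 0 replicate 2, day 16 replicate 1 or day 16 replicate 2 gave 774, 748, 1200 or 1313 shRNAs. At the level of targets, 2 fell and 5 rose. Circular target Pca-circ189 fell (median over its shRNAs −2.20, SD 1.90, adjusted p = 0.0443), as did Pca-circ1759 (median −1.62). Pca-circ1227 rose (median 1.52, SD 1.31, adjusted p = 0.0335), as did Pca-circ740 (median 1.38, SD 0.33, adjusted p = 0.0335). The call for Pca-circ189 ended without day 0 replicate 1 (0.116), day 16 replicate 1 (0.345) or day 16 replicate 2 (0.0738), and that for Pca-circ1227 without day 0 replicate 2 (0.0872), day 16 replicate 1 (0.158) or day 16 replicate 2 (0.0572). With the replicate block both ended (0.0992 and 0.0507), and with a mean count of at least 100 that for Pca-circ189 ended (0.0535). The count of 7 targets became 0 without day 16 replicate 1 and 1 without day 16 replicate 2.

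In LNCaP at day 16, SFRS1 fell by 3.26 ± 0.66 (SE, adjusted p = 0.000888), PSMD12 fell by 2.31 ± 0.47 (adjusted p = 0.00106) and RPS14 fell by 1.69 ± 0.33 (adjusted p = 0.000731). RBM17, a splicing factor, fell by 1.24 ± 0.28 (adjusted p = 0.00240), and UNK, an RNA-binding protein, fell by 4.12 ± 0.97 (adjusted p = 0.00330). Without 1 library the UNK value ranged from −10.7 to −3.18 and the PSMD12 value from −3.72 to −1.58. In all, 18 positive-control shRNAs fell, 12 adjusted over the list alone, and 1 against the ribosomal protein RPS15A rose, 0 adjusted over the list alone. Of these 19 calls, 14 ended without 1 library. In the library 14.2% of linear and 11.3% of circular shRNAs fell by edgeR, against 18% of positive controls. The count alone therefore sets the controls little apart from the library in this line. The RPS15A shRNA was at 0.92 ± 0.32 (adjusted p = 0.0355), and its call ended without day 0 replicate 1 (0.0631), day 0 replicate 2 (0.218) or day 16 replicate 2 (0.145), and with total counts (0.0759). Spliceosome members fell in 5 of 17, 5 adjusted over the list alone (camera adjusted p = 0.0117), but the call was lost with an estimated correlation (adjusted p = 0.0567 with an estimated correlation) and without day 16 replicate 2 (0.138). Translation factors fell in 2 of 6, 3 adjusted over the list alone (camera adjusted p = 0.0462), also lost with an estimated correlation (adjusted p = 0.0894 with an estimated correlation) and without day 0 replicate 1 (0.0707) or day 16 replicate 2 (0.0989). Ribosomal members fell in 4 of 31 (3 adjusted over the list alone, camera adjusted p = 0.362), proteasome members in 2 of 13 (1 adjusted over the list alone, camera adjusted p = 0.528) and nuclear transport in 0 of 5 by edgeR (camera adjusted p = 0.645, fry 0.0421).

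Over the whole LNCaP library, 1402 shRNAs fell and 1363 rose, 24.5% of those tested, against 649 called with the 6 libraries of the line alone. Scaled to the negative controls, 3527 fell and 185 rose. Lower calls were 50.7% before that scaling and 64.2% with total counts. Without day 0 replicate 1 or replicate 2 the count was 1682 or 1457. No target fell by rank aggregation of edgeR p-values, with 167 at an unadjusted p under 0.05, and 3 rose. Of the targets that rose, Pca-circ700 had a median of 1.42 (SD 0.12, adjusted p = 0.00984) and the linear target Pca-circ1315_linear 1.22 (SD 0.73, adjusted p = 0.0402). With DESeq2 p-values 5 targets passed, and limma on target means called 874. The call for Pca-circ700 ended without day 0 replicate 1 (0.0603) or day 16 replicate 1 (0.0717), and that for Pca-circ1315_linear without any 1 of the 4 libraries (0.0517 to 0.190) or with the replicate block (0.0625). The count of 3 targets was 0 without day 0 replicate 1 and 1 without either day 16 library.

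In 22Rv1 at day 16, RPL23A fell by 3.16 ± 0.41 (SE, adjusted p = 4.17e-05), SFRS1 fell by 3.61 ± 0.68 (adjusted p = 0.00118), EIF3B fell by 1.63 ± 0.25 (adjusted p = 0.000193) and CCT3 fell by 1.21 ± 0.24 (adjusted p = 0.00168). In all, 24 positive-control shRNAs fell, 26 adjusted over the list alone, and 20 of the 24 calls ended without 1 library. By edgeR 9.38% of linear and 6.23% of circular shRNAs fell, against 24% of positive controls. Spliceosome members fell in 6 of 17 (6 adjusted over the list alone, camera adjusted p = 0.00228) and translation factors in 3 of 6 (5 adjusted over the list alone, camera adjusted p = 0.00972). Proteasome members fell in 3 of 13, 4 adjusted over the list alone (camera adjusted p = 0.0147), a call lost with an estimated correlation (adjusted p = 0.0653 with an estimated correlation). Ribosomal members fell in 4 of 31, 5 adjusted over the list alone (camera adjusted p = 0.0379), lost with an estimated correlation (adjusted p = 0.0518 with an estimated correlation) and without day 16 replicate 2 (0.184). Nuclear transport fell in 1 of 5 (camera adjusted p = 0.101).

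Over the whole 22Rv1 library, 849 shRNAs fell and 821 rose, 14.8% of those tested, against 3349 called with the 6 libraries of the line alone. Scaled to the negative controls, 1898 were called with 1775 of them lower, and lower calls went from 50.8% to 93.5%. Without day 0 replicate 1, day 0 replicate 2, day 16 replicate 1 or day 16 replicate 2 the count was 452, 403, 833 or 760. By rank aggregation this line had the most called targets of the 4 lines, 7 lower and 16 higher. Limma on target means called 623 here, below LNCaP (874) and PC-3 (695). Pca-circ206 fell (median −1.79, SD 1.29, adjusted p = 0.00615), as did the linear target Pca-circ497_linear (median −1.42, SD 0.43, adjusted p = 0.0201). Pca-circ567 rose (median 1.24, SD 0.33, adjusted p = 0.00902), as did Pca-circ1148 (median 1.20, SD 0.21, adjusted p = 0.00492). Without day 16 replicate 2 the calls for Pca-circ206 (0.0953), Pca-circ567 (0.0733) and Pca-circ497_linear (0.216) ended, and the last also ended without day 0 replicate 2 (0.0570) or day 16 replicate 1 (0.223). The count of 23 targets was 11 without day 16 replicate 1 and 2 without day 16 replicate 2.

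In V16A at day 16, an shRNA against COPB1 fell by 4.97 ± 0.92 (SE, adjusted p = 0.00321), PLRG1 fell by 2.43 ± 0.39 (adjusted p = 0.00132), SNRPD2 fell by 2.29 ± 0.37 (adjusted p = 0.00118), an shRNA against PSMD1 fell by 1.92 ± 0.35 (adjusted p = 0.00306) and RBM17 fell by 1.66 ± 0.29 (adjusted p = 0.00220). In all, 24 positive-control shRNAs against 23 genes fell, 42 adjusted over the list alone, and 19 of the 24 calls ended without 1 library. By edgeR 3.38% of linear and 2.31% of circular shRNAs fell, against 24% of positive controls. Spliceosome members fell in 7 of 17 (11 adjusted over the list alone, camera adjusted p = 3.89e-07), proteasome members in 5 of 13 (6 adjusted over the list alone, 0.000189), ribosomal members in 4 of 31 (10 adjusted over the list alone, 0.000706) and translation factors in 2 of 6 (3 adjusted over the list alone, 0.00387). Nuclear transport fell in 1 of 5 (camera adjusted p = 0.101, and 0.0181 without day 16 replicate 2). Over the whole library 326 shRNAs fell and 200 rose, 4.65% of those tested; scaled to the negative controls, 1299 fell and 14 rose, and lower calls went from 62.0% to 98.9%. Without day 0 replicate 1, day 0 replicate 2, day 16 replicate 1 or day 16 replicate 2 the count was 88, 102, 868 or 292, and DESeq2 called 1192. No target passed by rank aggregation of edgeR p-values, with 170 lower and 173 higher at an unadjusted p under 0.05; DESeq2 p-values gave 1, limma on target means 359, and the edgeR fit without day 0 replicate 2 gave 1.

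**Figure D3:**
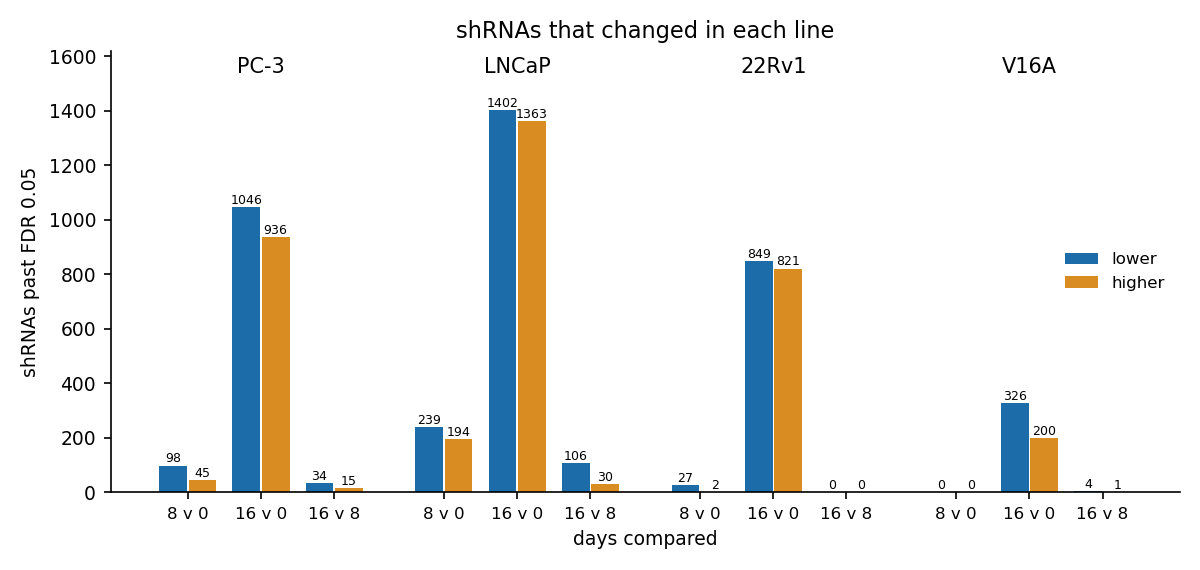
Number of shRNAs (vertical axis) past an adjusted p of 0.05 by edgeR, lower and higher, for each line and pair of days. In the fit of all 24 libraries LNCaP has the most at day 16 against day 0 (1402 lower, 1363 higher) and V16A the fewest (326 lower, 200 higher). With the 6 libraries of a line alone LNCaP has 649 and 22Rv1 3349, so the order depends on the fit.

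Averaged over the lines, 2530 shRNAs fell and 2417 rose, 43.8% of those tested; scaled to the negative controls, 5533 fell and 366 rose, and lower calls went from 51.1% to 93.8%. At the level of targets, 8 circular targets rose. Pca-circ1023 had a median of 0.95 (SD over shRNAs 0.17, adjusted p = 0.00984), with 0.81, 0.93, 0.79 and 0.79 in PC-3, LNCaP, 22Rv1 and V16A, and Pca-circ1148 a median of 0.84 (SD 0.17, adjusted p = 0.0201). No target fell by rank aggregation of edgeR p-values, with 203 at an unadjusted p under 0.05; DESeq2 p-values gave 8 called targets in both directions together, and limma on target means gave 1324. Of targets called in a single line, 2 that rose were shared by PC-3 and 22Rv1, against 0.0325 for independent lists (two-sided Fisher exact test, adjusted p = 0.00235 over 6 pairs of lines). Targets that fell were too few to compare, with 0 in LNCaP and in V16A and 0.00569 expected to be shared by PC-3 and 22Rv1. For single shRNAs, 37 fell in all 4 lines against 0.281 for independent lists and 34 rose in all 4 against 0.145. Changes at day 16 correlated between lines at r = 0.385 to 0.515 across shRNAs, which are not independent replicates.

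The comparison of day 8 with day 0 asks how early the losses appear. By day 8, DDX23 had changed by −2.07 in PC-3 and −1.35 in LNCaP (edgeR adjusted p = 0.00789 and 0.0359), and EIF3B by −1.16, −1.02 and −1.17 in PC-3, LNCaP and 22Rv1 (adjusted p = 0.0195, 0.0225 and 0.0352). PSMD12 had changed by −2.56 in LNCaP (adjusted p = 0.00532) and RPL23A by −2.11 in 22Rv1 (adjusted p = 0.0121). At day 8, 10 positive-control shRNAs had fallen in PC-3, 7 in LNCaP, 5 in 22Rv1 and 0 in V16A (21, 16, 37 and 24 adjusted over the list alone), and the RPS15A shRNA had risen in LNCaP by 1.14, a call that ended with total counts (0.0536). Each of these single calls ended without at least 1 library, with EIF3B in PC-3 at 0.162 without day 0 replicate 1, at 0.160 without day 0 replicate 2 and at 0.176 without day 8 replicate 2. The whole library gave 98 lower and 45 higher shRNAs in PC-3, 239 and 194 in LNCaP, 27 and 2 in 22Rv1 and 0 in V16A, where 501 had an unadjusted p under 0.05 and DESeq2 called 29.

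Day 8 shRNA counts rested on single libraries. The 143 in PC-3 became 0 without either day 0 library and 4 without day 8 replicate 2. The 433 in LNCaP became 130, 27, 193 and 137 without day 0 replicate 1, day 0 replicate 2, day 8 replicate 1 and day 8 replicate 2, and the 29 in 22Rv1 became at most 1 without any 1 library. With the negative-control scaling, lower calls went from 68.5% to 98.5% in PC-3 and from 55.2% to 99.0% in LNCaP. Of circular and linear targets, 1 fell in PC-3, 3 fell in LNCaP, 7 fell and 2 rose in 22Rv1 and 2 fell in V16A, where 1 positive-control gene also fell as a target. In 22Rv1, Pca-circ497_linear (median −1.06, adjusted p = 0.0418) and Pca-circ206 (median −0.96, adjusted p = 0.0305) had fallen and Pca-circ1148 had risen (median 0.75, adjusted p = 0.0283). The 9 called targets of 22Rv1 became 0 without day 8 replicate 1 and 4 without day 8 replicate 2. The 3 of V16A, the positive-control gene included, became 1 without any 1 library. The 3 of LNCaP became 0 without day 0 replicate 1 and 1 without day 0 replicate 2 or day 8 replicate 1, and the 1 of PC-3 became 2 without either day 0 library and 0 without either day 8 library.

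Between day 8 and day 16 no positive-control shRNA passed in any line by edgeR, and the positive-control medians were 0.06, 0.04, 0.18 and −0.03 in PC-3, LNCaP, 22Rv1 and V16A. Over the library, 34 shRNAs fell and 15 rose in PC-3, 106 and 30 in LNCaP, 4 and 1 in V16A and 0 in 22Rv1, where 891 had an unadjusted p under 0.05 and DESeq2 called 103. Replicates of the same number deviated together at these days, and a fit of days 8 and 16 alone with the replicate block, chosen after the data were seen, called 0 shRNAs in PC-3, 34 in LNCaP and 2 in V16A. Without day 16 replicate 1, day 16 replicate 2, day 8 replicate 1 or day 8 replicate 2, the counts were 13, 24, 52 and 3 in PC-3, 1010, 609, 90 and 90 in LNCaP, 0, 2, 0 and 0 in 22Rv1, and 205, 1, 1 and 1 in V16A. Lower calls made up 69.4% in PC-3, 77.9% in LNCaP and 80.0% in V16A, and 95.7%, 97.1% and 91.7% when scaled to the negative controls; with total counts PC-3 had 90.0% and LNCaP 89.3%. No target passed in PC-3, LNCaP or V16A (142 lower and 157 higher, 116 and 126, 152 and 143 at an unadjusted p under 0.05; DESeq2 p-values gave 0 in each), while limma on target means called 6, 76 and 7. In 22Rv1, 2 targets rose, against 8 called with the block of days 8 and 16, 9 with the block in all 24 libraries, and 0 without either of day 16 replicate 2 and day 8 replicate 1.

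Whether lines differ was tested as the difference of their day 16 changes. Among the positive controls, 1 of 2 COPB1 shRNAs differed between LNCaP and V16A by 5.48 ± 1.16 log2 units (SE, edgeR adjusted p = 0.0111), at 0.50 in LNCaP and −4.97 in V16A, and 1 of 2 PSMD1 shRNAs by 2.51 ± 0.48 (adjusted p = 0.00644), at 0.59 and −1.92. The other COPB1 and PSMD1 shRNAs differed by 1.07 and 0.56 without passing (adjusted p = 0.279 and 0.578). VCP differed between PC-3 and LNCaP by −2.39 ± 0.71 (adjusted p = 0.0479), and RBM17 between 22Rv1 and V16A by 1.74 ± 0.40 (adjusted p = 0.0349). The COPB1 difference ended without LNCaP day 0 replicate 2 (0.0741) or V16A day 0 replicate 1 (0.0522), the PSMD1 difference without V16A day 0 replicate 1 (0.0501), the VCP difference without any 1 of 7 of the 8 libraries and the RBM17 difference without any 1 of 6 (adjusted p up to 0.187 and 0.203). Across the library, 592 shRNAs differed between PC-3 and LNCaP, 222 between PC-3 and 22Rv1, 245 between PC-3 and V16A, 288 between LNCaP and 22Rv1, 324 between LNCaP and V16A and 94 between 22Rv1 and V16A.

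Targets that differed between lines were few: 4, 5, 2, 0, 4 and 1 for those pairs in the same order. For LNCaP and 22Rv1, where edgeR p-values gave 0, 147 and 158 targets had an unadjusted p under 0.05 in the 2 directions, and the fit with the replicate block gave 1. Pca-circ315 differed most clearly between 22Rv1 and V16A (median difference −1.59, adjusted p = 0.00246) and Pca-circ1193 between LNCaP and V16A (1.36, adjusted p = 0.00246); both calls held without any 1 of the 8 libraries. LNCaP, 22Rv1 and V16A together were also set against PC-3. There 419 shRNAs and 2 targets differed, Pca-circ1759 by 1.34 (adjusted p = 0.0123) and Pca-circ1232_linear by −1.17 (adjusted p = 0.0221). Without PC-3 day 16 replicate 2 both calls ended (0.216 and 0.0664), and that for Pca-circ1759 also ended without PC-3 day 0 replicate 2 (0.0566), PC-3 day 16 replicate 1 (0.0508) or LNCaP day 16 replicate 1 (0.0738).

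Circular and linear targets were then compared with each other. Single shRNAs against linear targets fell more often than those against circular targets, at 12.5% against 7.29% in PC-3, 14.2% against 11.3% in LNCaP, 9.38% against 6.23% in 22Rv1, 3.38% against 2.31% in V16A and 26.2% against 19.6% in the mean of the lines (two-sided Fisher exact tests over shRNAs, adjusted p = 2.17e-18, 1.78e-05, 3.05e-09, 0.00102 and 3.24e-15). In PC-3 linear shRNAs also rose more often, at 9.73% against 7.57% (adjusted p = 0.000446), and the shares that rose did not pass in the other lines or the mean (adjusted p from 0.172 to 0.651). Targets called lower were too few to compare by class. They were 2 circular and 0 linear in PC-3, 6 and 1 in 22Rv1, and 0 of both in LNCaP, V16A and the mean. No difference passed. Targets that rose were circular in 22Rv1, 16 of 1508 against 0 of 933 linear (adjusted p = 0.00252). The same test did not pass in PC-3 (5 against 0, adjusted p = 0.273) or the mean of the lines (8 against 0, adjusted p = 0.0683). Nor did it in LNCaP (2 against 1) or V16A (0 in both). With targets called at 0.25, Fisher's test passed in PC-3 (42 against 6, adjusted p = 0.000204), 22Rv1 (65 against 9, 3.24e-06) and the mean (56 against 9, 5.71e-05). It did not pass in LNCaP (10 against 3, 0.490) or V16A (2 against 0, 0.528). Single shRNAs in 22Rv1 rose in 7.03% of the circular and 7.84% of the linear class (Fisher's test, adjusted p = 0.172). There the changes of shRNAs of 1 target had an intraclass correlation of 0.262 for circular and 0.0269 for linear targets. Of circular targets 1329 of 1508 have 5 shRNAs, and of linear targets 560 of 933. Rank aggregation scores shRNAs of 1 target together, so the target counts cannot separate a class effect from these differences. Targets and shRNAs of 1 library are not replicates of the experiment, so these p-values describe this library.

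Whether a circular RNA and the linear RNA of the same number deplete together was tested over 891 pairs. Their median changes had r = 0.0139 in PC-3, −0.0398 in LNCaP, −0.0228 in 22Rv1, −0.0156 in V16A and −0.0496 in the mean of the lines (two-sided permutation tests across pairs, adjusted p from 0.594 to 0.677, Spearman's rho from −0.0525 to −0.00282). The shRNAs of 1 linear target agreed so little in their changes (intraclass correlation 0.00590 to 0.0269 over the lines and the mean) that these values do not show whether partners deplete together. In 22Rv1, Pca-circ497_linear fell while its circular partner Pca-circ497 was at −0.89. No pair had both members called lower in any line, at an adjusted p of 0.05 or of 0.25, by rank aggregation of edgeR p-values, but too few members were called for this to exclude shared loss.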

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

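The tests of positive-control shRNAs in this part were run per shRNA because most control genes have 1 shRNA, a choice made after the table was seen; the tests of targets and of line differences were planned. Each result here is a difference between 2 lines, or between PC-3 and the other lines, in the change from day 0 to day 16 that passed the test of the difference itself. The difference of a target is the median over its shRNAs of their own differences, so it need not equal the difference of the 2 medians beside it. Values are log2 units, adjusted p-values are from edgeR (for targets, rank aggregation of its p-values), and the libraries whose loss ends a call are given as counts with the highest adjusted p. Other processing (median-ratio factors, total counts, a mean count of at least 100, DESeq2 and the replicate block) ended a call only where stated. No explanation was tested for these differences.

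Among positive controls, 1 of 2 shRNAs against COPB1 of the COPI coat differed by 5.48 between LNCaP (0.50) and V16A (−4.97), and the call ended without 2 of the 8 libraries, LNCaP day 0 replicate 2 (0.0741) and V16A day 0 replicate 1 (0.0522). 1 of 2 shRNAs against PSMD1 of the proteasome differed by 2.51 between LNCaP (0.59) and V16A (−1.92), ending without V16A day 0 replicate 1 (0.0501). The other shRNA of each gene did not pass (1.07 for COPB1 and 0.56 for PSMD1, adjusted p = 0.279 and 0.578). RBM17, a splicing factor, differed by 1.74 between 22Rv1 (0.08) and V16A (−1.66), ending without 6 of 8 libraries (up to 0.203, without V16A day 0 replicate 1). VCP differed by −2.39 between PC-3 (−2.40) and LNCaP (−0.02), ending without 7 of 8 libraries (up to 0.187, without LNCaP day 0 replicate 2), with total counts (0.0526) and with the replicate block (0.0522).

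Between PC-3 and LNCaP, Pca-circ1759 differed by −1.47 (medians −1.62 and 0.59, adjusted p = 0.0492), ending without 2 of 8 libraries (up to 0.195, without PC-3 day 16 replicate 2). Pca-circ1369 differed by −1.38 (−0.56 and 0.75, adjusted p = 0.0492), ending without 5 (up to 0.389, without LNCaP day 16 replicate 2). Pca-circ1232_linear differed by 1.95 (0.56 and −0.67, adjusted p = 0.0406), ending without 6 (up to 0.660, without LNCaP day 16 replicate 1), and Pca-circ1020 by 1.77 (0.80 and −0.55, adjusted p = 0.0406), ending without 7 (up to 0.282, without LNCaP day 16 replicate 2). All 4 calls ended with total counts (0.0517 to 0.0566), those of Pca-circ1759 and Pca-circ1369 with a mean count of at least 100 (0.0559), and those of Pca-circ1232_linear and Pca-circ1020 with DESeq2 (0.0566 and 0.0754). The 4 called targets of this pair became 0 without LNCaP day 16 replicate 1 and 7 without PC-3 day 0 replicate 2.

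Between PC-3 and 22Rv1, Pca-circ189 differed by −1.91 (−2.20 and 0.34, adjusted p = 0.0221) and Pca-circ1759 by −1.33 (−1.62 and 0.01, adjusted p = 0.0221). They ended without 4 and 3 of 8 libraries (up to 0.144 and 0.135, both without PC-3 day 16 replicate 1). Pca-circ497 differed by 2.02 (1.03 and −0.89, adjusted p = 0.00492) and Pca-circ237 by 1.64 (−0.03 and −1.67, adjusted p = 0.00984), each ending only without 22Rv1 day 16 replicate 2 (0.10).

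Between PC-3 and V16A, Pca-circ204 differed by 0.96 (0.67 and −0.30, adjusted p = 0.0406), ending without 7 of 8 libraries (up to 0.344, without V16A day 16 replicate 2). Pca-circ1232_linear differed by 0.77 (0.56 and −0.13, adjusted p = 0.0406), ending without 5 (up to 0.476, without V16A day 16 replicate 1). Both calls ended with median-ratio factors (0.0603), a mean count of at least 100 (0.0583) and DESeq2 (0.0738 and 0.108), and that of Pca-circ1232_linear with the replicate block (0.0529). Between LNCaP and V16A, Pca-circ1137 differed by 1.47 (median 0.02 in V16A and higher in LNCaP, adjusted p = 0.0326), ending without 6 (up to 0.467, without LNCaP day 0 replicate 1) and with the replicate block (0.0566), and Pca-circ1193 by 1.36 (0.72 and −0.64, adjusted p = 0.00246), ending without 0 of 8. Between 22Rv1 and V16A, Pca-circ315 differed by −1.59 (−0.81 and 0.78, adjusted p = 0.00246), also ending without 0 of 8.

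With LNCaP, 22Rv1 and V16A set against PC-3, Pca-circ1232_linear differed by −1.17 (adjusted p = 0.0221), ending without PC-3 day 16 replicate 2 (0.0664), 1 of 16 libraries. Pca-circ1759 differed by 1.34 (adjusted p = 0.0123), ending without 4 of 16 (up to 0.216, without PC-3 day 16 replicate 2).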

How the results depend on the processing

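Scaling to the negative controls, the fit of days 8 and 16 alone with a block, and other scalings of the control difference were chosen after the data were seen, as was the rule that a change of sign counts as reversed when only the alternative passes. The other alternatives here were planned. The main results moved or changed call in most cases with looser thresholds (26 moved and 6 the same at 0.25, 17 and 9 at 0.1), limma on target means (12 and 1) and the libraries of a line alone (15 and 9), and seldom with median-ratio factors (1 and 46), total counts (3 and 31) or a mean count of at least 100 (1 and 25). A count that moved differs by over 1.5 times; unless a sentence says otherwise, the cause was not tested. Over all alternatives, libraries left out included, named targets kept their call and direction in 472 fits, lost the call in 89 and gained it in 8. Control shRNAs named for the mean of the lines or a line difference kept theirs in 660, lost it in 18 and gained it in 4, and those called in 1 line kept it in 708 and lost it in 291. Depth limits the shRNAs of low count, and the filter for low counts removed 0 shRNAs, so the fit without it is the same fit. Factors from at least 20 control shRNAs were not run because 6 negative controls exist, and a mean over several circular targets of 1 host was not run because each number has 1 circular target. In fits without 1 library the lone library of its group is assumed to vary like the other groups.

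A looser threshold calls more by construction. At an adjusted p of 0.25, shRNAs numbered 4586 in PC-3, 5520 in LNCaP, 4281 in 22Rv1 and 2357 in V16A at day 16 against day 0. They numbered 1438, 2442, 630 and 5 at day 8 against day 0, and 456, 1159, 44 and 99 at day 16 against day 8. Targets numbered 61, 15, 93 and 17, then 21, 20, 30 and 22, then 12, 1, 38 and 1, and 82 in the mean of the lines. The circular minus linear share of depleted targets in V16A became 0.755 percentage points and did not pass (adjusted p = 0.116), and 4 targets were depleted in at least 2 lines. At 0.1, shRNAs numbered 1007 in V16A at day 16, 356, 925, 136 and 3 at day 8, and 96, 315, 1 and 15 at day 16 against day 8. Targets numbered 19, 10, 40 and 4 at day 16, 5 in LNCaP at day 8, 1 and 16 in LNCaP and 22Rv1 at day 16 against day 8, and 30 in the mean.

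The replicate block in all 24 libraries gave 3 targets in PC-3 at day 16, 1 in LNCaP at day 8, 1 in V16A at day 8 and 9 in 22Rv1 at day 16 against day 8. It gave 65 shRNAs in 22Rv1 and 1 in V16A at day 8, 1 target for PC-3 minus V16A, 1 for LNCaP minus 22Rv1, and an adjusted p of 0.0320 for ribosomal proteins in PC-3. Day 0 libraries are not paired by number, so in contrasts with day 0 the block uses up degrees of freedom and a lost call need not mean a weaker effect. The cause of lost and gained calls was not tested. With days 8 and 16 alone and the block, day 16 against day 8 gave 0 shRNAs in PC-3, 34 in LNCaP, 2 in V16A and 8 targets in 22Rv1. The block changed no other call of a list.

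DESeq2 Wald tests called 1192 shRNAs in V16A at day 16, 694, 1187, 374 and 29 in PC-3, LNCaP, 22Rv1 and V16A at day 8, and 282, 600, 103 and 125 at day 16 against day 8. Its targets numbered 5 in LNCaP and 1 in V16A at day 16 and 0 in LNCaP at day 8. The 6 libraries of the line alone leave fewer degrees of freedom and take the spread from that line only, and they moved counts both ways. They gave 649 shRNAs in LNCaP and 3349 in 22Rv1 at day 16, 0, 0 and 296 in PC-3, LNCaP and 22Rv1 at day 8, and 0, 0, 1 and 0 in PC-3, LNCaP, 22Rv1 and V16A at day 16 against day 8. Their targets numbered 6 in LNCaP and 1 in V16A at day 16, 1 in LNCaP and 1 in V16A at day 8, and 1 in LNCaP and 0 in 22Rv1 at day 16 against day 8.

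Scaled to the 6 negative controls, shRNAs numbered 1313 in V16A at day 16, 391, 1083, 538 and 12 at day 8, and 272 in LNCaP and 12 in V16A at day 16 against day 8. Targets numbered 6 in LNCaP and 19 in the mean at day 16, and 1, 3 and 1 in LNCaP, 22Rv1 and V16A at day 8. With total counts alone shRNAs numbered 55 in 22Rv1 at day 8, and 1 and 8 in 22Rv1 and V16A at day 16 against day 8. A mean count of at least 100 left 0 targets in LNCaP at day 8. Median-ratio factors left 0 targets for PC-3 minus V16A.

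With alpha 0.05 targets numbered 2, 6 and 1 in PC-3, 22Rv1 and V16A and 5 in the mean at day 16, 0 and 1 in LNCaP and 22Rv1 at day 8, and 1 in 22Rv1 at day 16 against day 8. With alpha 1, or with at least 3 shRNAs per target, V16A had 1 at day 16. A Stouffer sum gave 16 in PC-3, 5 in V16A and 25 in the mean at day 16, 5 in V16A at day 8, and 1 and 19 in PC-3 and 22Rv1 at day 16 against day 8. Limma on target means, which does not compare a target with the rest of the library, called 695, 874, 623 and 359 and 1324 in the mean at day 16. It called 164, 265 and 84 in PC-3, LNCaP and 22Rv1 at day 8, and 6, 76, 13 and 7 at day 16 against day 8.

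With single shRNAs as the unit, the circular minus linear share of depletion was −5.17 percentage points in PC-3 and −3.15 in 22Rv1, the reverse in sign of 0.133 and 0.291 for targets. It was −2.83 in LNCaP, −1.06 in V16A and −6.58 in the mean, where targets had given 0 and the shRNA difference passed. With an estimated correlation the adjusted p rose past 0.05 for translation factors in PC-3 (0.0653) and LNCaP (0.0894), spliceosome in LNCaP (0.0567), ribosomal proteins in 22Rv1 (0.0518) and proteasome in 22Rv1 (0.0653) and the mean (0.0881). Fry, which tests each list alone, passed for ribosomal proteins (3.46e-06) and proteasome (0.00273) in PC-3 and for both in LNCaP (2.69e-05 and 0.00273). It passed for nuclear transport in PC-3 (0.0220), LNCaP (0.0421), 22Rv1 (0.000310), V16A (0.00222) and the mean (1.77e-05), and for controls in no list in LNCaP (5.43e-05). Against all targets as background, ribosomal proteins in PC-3 passed (0.0134).

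Leaving out 1 library of a contrast gave these ranges. Called shRNAs ranged over 748 to 1313 in PC-3, 1457 to 3164 in LNCaP, 403 to 833 in 22Rv1, 88 to 868 in V16A and 4292 to 5384 in the mean at day 16. At day 8 they ranged over 0 to 170, 27 to 193, 0 to 1 and 0 to 1, and at day 16 against day 8 over 3 to 52, 90 to 1010, 0 to 2 and 1 to 205. Called targets ranged over 0 to 5, 0 to 3, 2 to 28, 0 to 1 and 7 to 12 in the mean at day 16. At day 8 they ranged over 0 to 2, 0 to 3, 0 to 9 and 1 to 1, and at day 16 against day 8 over 0 to 3, 0 to 1, 0 to 3 and 0 to 0. For line differences, targets ranged over 0 to 7 (PC-3 minus LNCaP), 3 to 8 (PC-3 minus 22Rv1), 0 to 2 (PC-3 minus V16A), 1 to 4 (LNCaP minus V16A), 1 to 2 (22Rv1 minus V16A) and 0 to 4 (PC-3 against the rest). The cause of each move was not tested.

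List adjusted p-values that crossed 0.05 ranged over 0.0172 to 0.239 for ribosomal proteins and 0.0140 to 0.0645 for translation factors in PC-3. In LNCaP they ranged over 0.00150 to 0.138 for spliceosome, 0.0140 to 0.0989 for translation factors and 0.0103 to 0.0675 for all positive controls. They ranged over 0.0117 to 0.184 for ribosomal proteins in 22Rv1 and 0.0181 to 0.490 for nuclear transport in V16A. The positive minus negative control difference at day 16 ranged over −1.43 to −1.17 in PC-3, −1.31 to −1.03 in LNCaP, −1.72 to −1.31 in 22Rv1 and −1.65 to −1.59 in V16A. At day 8 it ranged over −1.45 to −1.10, −1.34 to −0.91, −1.72 to −1.55 and −1.46 to −1.36. Pair correlations stayed between −0.0595 and 0.0311, with p by Fisher's z in these fits.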

Other observations

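Chosen after the result was seen were the tests of sequence overlap, of noise in linear shRNAs, of random sets of shRNAs and of a common shift within single lines, and the reading of the class gap against its spread; the tests of abundance, of a common shift in the mean of the lines, of resampled targets and the splits of libraries were set beforehand. The interval around the class gap was brought in after its point values had been seen. By the earlier reading, against 50% of the gap, abundance had counted as an account of it.

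The positive controls that belong to none of the fixed lists were lost too, averaged over the lines, in 12 of 20 shRNAs (15 adjusted over the list alone, median −0.90, camera adjusted p = 0.00372). CCT3 and CCT8, subunits of the TRiC chaperonin that folds actin and tubulin, fell by 1.07 ± 0.12 and 1.80 ± 0.24 log2 units (SE, edgeR). NHP2L1, a protein of the U4 small nuclear ribonucleoprotein, fell by 1.66 ± 0.30, WBP11, a splicing factor, fell by 2.04 ± 0.51 and VCP fell by 1.29 ± 0.25. CCNB3, a B-type cyclin, fell by 2.17 ± 0.41, UNK fell by 2.30 ± 0.45, LCN10 fell by 1.45 ± 0.37 and ZNF174 fell by 1.27 ± 0.32. ITGA2 (−0.75), RBMXL1 (−0.72), MYO3B (−0.53) and C22orf27 (0.34) did not pass. The 20 genes of this group have 1 shRNA each, so loss of the gene cannot be told apart from an off-target effect of its shRNA.

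Of 100 splits of the 16 day 0 and day 16 libraries with a term for each line, the real one included, 1 gave as many shRNAs as the real 3931, and the highest other gave 133. For targets 1 split gave as many as the real 20, with 4 as the highest other. These counts come from the fit of 16 libraries, and the fit of 12 groups gave 4947 shRNAs and 8 targets. The other splits mix the days, which leaves the change over days in the residual and keeps their counts low. They were also not balanced within lines, as the real split is, which can lower their counts further. Ranking first was therefore favoured by the design, and the rank does not measure how strong the difference between the days is. Nor does it show that the difference would repeat in separate infections. Splits with as small a camera p were counted for each list. They numbered 1 for translation factors (real 0.00161, smallest other 0.00209), 3 for ribosomal proteins (0.00112, 9.95e-05) and 2 for all positive controls (4.47e-10, 4.85e-12). Controls in no list had 4 (0.000133, 3.05e-05), spliceosome 5 (1.52e-06, 5.08e-08), proteasome 17 (0.0102, 3.12e-05) and nuclear transport 16 (0.0817, 0.00395). By the rule set beforehand, 5 or more of the 100 splits left chance as an account. This held for spliceosome, proteasome and nuclear transport. The other splits put 2 to 6 day 16 libraries in the first group, so some carry part of the real change. The camera p also has no direction, so these counts do not settle chance for any list. Camera sets a list against other targets of the same split, so a few libraries that differ in these genes can give a small p in another split.

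The shRNAs of 1 circular target moved together more than those of 1 linear target, with an intraclass correlation in the mean of the lines of 0.275 (95% interval 0.252 to 0.300) against 0.0263 (−0.000950 to 0.0534). More noise in linear shRNAs is argued against, since linear shRNAs correlated better between lines in 6 of 6 pairs of lines, and shared starting abundance left a gap of 0.232 of 0.249 after its trend was removed. Sequence overlap across the junction is a candidate explanation that stays open: shRNAs of neighbouring numbers in a target correlated more than distant ones (rank correlation of number distance and r −0.661, exact one-sided p = 0.0333 over 120 orderings). Shared off-target effects of overlapping shRNAs and loss of the circular RNA itself may both give this, and the table does not hold the sequences that would part them.

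Linear shRNAs were called lower more often than circular ones, by 6.58 percentage points in the mean of the lines. A few targets with several depleted shRNAs are argued against, since resampling whole targets gave an interval from 4.75 to 8.41. A shift common to all linear shRNAs is argued against as the whole cause in PC-3, where linear shRNAs also rose more often, by 2.16 percentage points (95% interval 0.960 to 3.35). In PC-3 taking off each class median left 54.0% of the gap (39.0 to 64.4), on both sides of 50%, so that share alone does not decide. Such a shift is also argued against in V16A, where 0.912 of 1.06 points was left (86.0%, 95% interval 54.5 to 99.3). A common shift stays a candidate explanation in the mean of the lines and in LNCaP. In the mean, with each class median taken off the gap was 1.72 (95% interval −0.0855 to 3.53), which left 26.2% of the whole gap (95% interval −1.63 to 43.0, all under 50%). In LNCaP 0.652 of 2.83 points was left (23.0%, −48.9 to 49.7), and in 22Rv1 1.01 of 3.15 was left (32.1%, −4.56 to 51.1), so in 22Rv1 a shift cannot be told apart from another cause. Day 0 abundance in the mean of the lines, with medians of 6.51 and 6.16 log2 CPM for linear and circular shRNAs, cannot be told apart from a class effect, because the gap within deciles was 3.04 (95% interval 1.08 to 4.97), which left 46.2% with an interval of 22.3 to 60.4 on both sides of 50%. These shares were taken within each resampling of targets. A biological difference between linear and circular RNA loss was not tested apart from these.

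The negative controls lay above the centre of the library, with a median of 0.35 in the mean of the lines. Abundance is argued against, since library shRNAs of the same day 0 abundance had a mean of −0.10. Chance with 6 shRNAs stays open, as random sets of 6 had as high a median with a share of 0.103. The smallest shares in a single line were 0.00419 in 22Rv1 and 0.00798 in V16A at day 8 (adjusted p = 0.0519 in both) and 0.0221 in V16A at day 16 (adjusted p = 0.0958), none past the threshold over 13 comparisons. No biological explanation was tested for it, and the share of library shRNAs that lower growth may also set where the centre lies.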
